A study of Mus musculus with 10 samples.

How the data were processed

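RNA from the striatum of R6/2 mice and of isogenic wild-type control mice, harvested at 11 weeks of age, was sequenced. R6/2 is a transgenic mouse model of Huntington's disease that carries a fragment of the human huntingtin gene with an expanded CAG repeat. The series holds 10 libraries, 5 in each group. Per the labels' protocols, RNA was purified with a Qiagen lipid tissue kit, amplified with the NuGEN Ovation RNA-Seq v2 system, turned into libraries by the Nextera method and sequenced on an Illumina HiSeq 2000. The labels do not state that each library came from its own animal, so the p-values measure the spread between these samples, which may be partly technical.

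The authors deposited 1 table of FPKM values (fragment counts scaled by transcript length and by the total of mapped fragments), with 1 column per library and 47632 gene rows named by versioned Ensembl gene IDs. Per the submitters' processing notes, STAR 2.4.0, Cufflinks and Cuffdiff were used with the mouse build GRCm38. The role of each tool, the annotation release, the strand setting and any scaling between libraries are not given in the sources used here. A second file that the labels name was not analysed here. FPKM values are not counts, and their low values did not fall on steps of whole reads, so the depth of each library is unknown and no counting interval is given. The values summed to between 1545169 and 2309123 per library, because short RNA genes have very high FPKM. Gm23935, annotated as a microRNA gene, alone held 44.8 ± 1.5% of the total in controls and 47.7 ± 2.88% in R6/2 (SD, n = 5).

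Symbols, positions and biotypes came from the GENCODE annotation of GRCm38, matched by stable Ensembl ID. Of the 47632 IDs 47220 had a symbol, and 39102 also matched in version. Columns were tied to samples by the names in the sample descriptions, and 0 columns of per-sample values were left without a sample. Of 77 cytosolic ribosomal protein genes, 13 were at 0 or below 1e-6 FPKM in at least 1 library, so an exact 0 can be a failed estimate and such a gene is only said to be listed at 0. Among the tested genes, 564 had a value above 0 in 1 library only.

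Genes with a mean of at least 1 FPKM over the 10 libraries (15905) were tested with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, on log2(FPKM + 1), R6/2 minus control, two-sided. The threshold was a Benjamini-Hochberg adjusted p of 0.05. All log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The fit had 8 residual degrees of freedom and a median of 1.77 prior degrees of freedom. The same limma model was tried on simulated independent normal values with 200 changed genes among 15905. It called 16.4%, 47.8% and 81.8% of genes changed by 0.5, 1 and 2 on the log2 scale, and 4 of 15705 unchanged genes. In the data 2244 genes were called, so these shares do not give the share of true changes found in the real comparison. Single values per library were compared with exact permutation tests over all splits into 5 and 5, two-sided, for which the smallest possible p is 0.00794.

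Before the data were examined, 30 gene lists, the tests, the rule for named genes and most alternatives were fixed. The lists held markers of direct-pathway, indirect-pathway and all spiny neurons, interneurons, astrocytes, myelin, oligodendrocyte precursors, microglia, endothelial and mural cells, choroid plexus, cortical, thalamic and hypothalamic neurons and blood cells. They also held immediate early, circadian clock, developmental transcription factor, cholesterol synthesis, respiratory chain, mitochondrially encoded, ribosomal protein, proteasome, heat shock, endoplasmic reticulum stress, p53 target, interferon-response, reactive astrocyte, glutamate receptor, GABA receptor, potassium channel and neuropeptide genes. The 29 lists with 3 or more tested members were tested with camera, which compares a list with the other tested genes, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and the self-contained test fry were alternatives. Exact tests of each list's mean per library and the tests of gene families that share a symbol root were added after the results were seen.

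The genes named are, first, the 12 largest rises and the 12 largest falls among genes that passed the threshold and whose groups did not overlap, leaving out unnamed gene models and small structural RNAs. Next come 11 genes named whatever their result (Htt, Gm12695, Drd1, Drd2, Adora2a, Penk, Ppp1r1b, Pde10a, Cnr1, Gfap and Kcnj10), and the 3 tested members of each list with the smallest p. Some genes that meet these rules are not reported here. Slc17a7, Ndufb6, Rpl39, Kcnj3, Kcnj6, Dhcr7, Fdft1, Ifit3, Ifitm3, Ifi27, Gm25177, Eif2s3y and the members of the Rgs, Polr and Pcdhb families were chosen after their values were seen. Of the 109 genes named by the rule, 11 have an exon that overlaps a gene with a mean of at least 1 FPKM, which reads without strand cannot tell apart: Ppp1r1b, Slc1a2, P2ry12, Rarres2, Atp5d, Rpl5, Psmc3, Ddit3, Cp, Gabra4 and Pcsk2. Haemoglobin, ribosomal protein, Ifit3 and class I histocompatibility genes have near-identical copies or pseudogenes, so their values are uncertain.

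The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, limma without the trend, array weights, the replicate number as a block, and leaving out each library in turn. An adjustment for the signal of 4 cortical genes (Slc17a7, Neurod6 and Tbr1 among them) and a rescaling of the protein-coding genes without the mitochondrial genome to 1 total per library were added after the data had been seen, and the 4 genes were chosen after their values were seen. Labels give no batch, litter or sex. Tables were handled with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9.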

Results

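Gene expression was measured by RNA sequencing in the striatum, the deep forebrain region that degenerates first in Huntington's disease, of 5 R6/2 and 5 control mouse samples at 11 weeks of age. The comparison asks which transcripts differ between the disease model and its isogenic controls at this age. Values are FPKM as deposited, and the sequencing depth of each library is unknown. The number of genes with at least 1 FPKM was 14698 ± 119 in control and 14488 ± 179 in R6/2 libraries (SD, n = 5, exact permutation test, two-sided, p = 0.0635). The mitochondrial genome held 30.7 ± 2.07% of all FPKM in controls and 26.0 ± 3.34% in R6/2 (SD, n = 5, exact permutation test, two-sided, p = 0.0317). Over the 4 such library measures compared, including total FPKM and the share of the most abundant gene, no difference passed Benjamini-Hochberg adjustment (0.106 for these 2, exact permutation test). A further measure was not among the 4. The total FPKM of protein-coding genes outside the mitochondrial genome was 211209 to 219426 in controls and 193203 to 202906 in R6/2, without overlap.

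**Figure D1:**
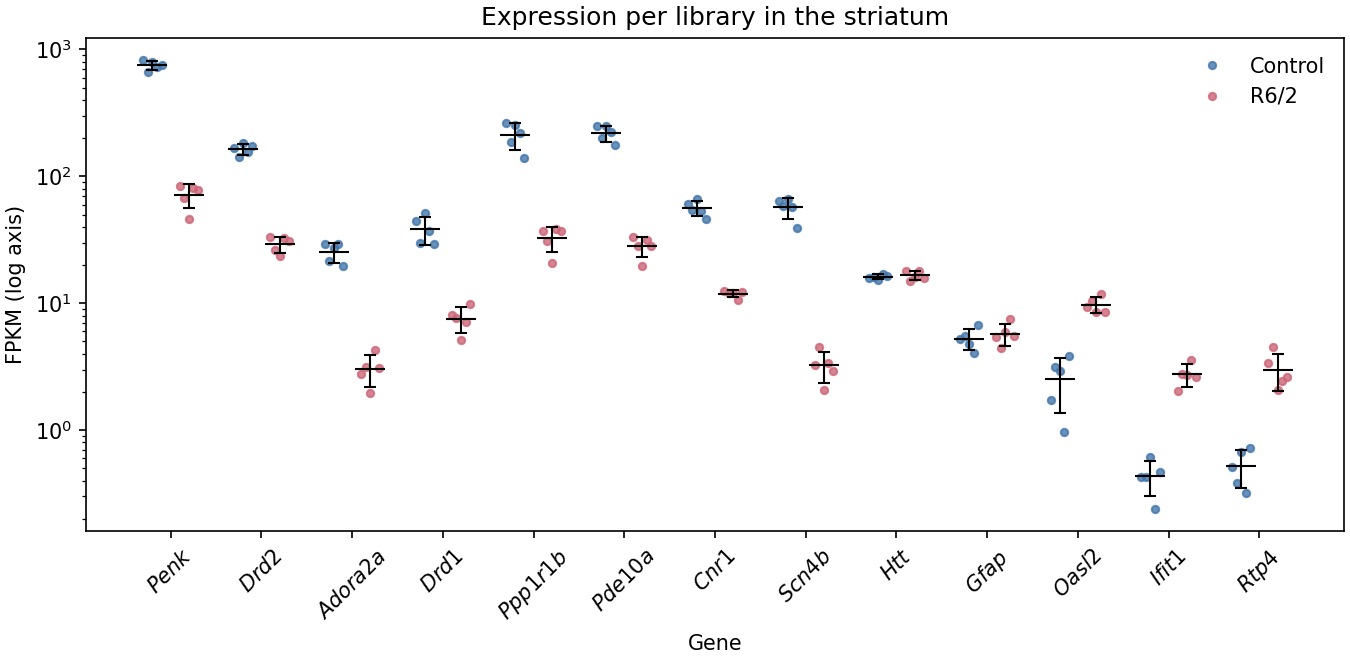
FPKM in each of the 5 control and 5 R6/2 libraries for selected genes, with bars for the group mean and SD. Penk, Drd2 and Pde10a lie lower in all R6/2 libraries than in all controls, and Oasl2 lies higher.

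R6/2 striatum lost transcripts of spiny projection neuron signalling and gained transcripts of the interferon response. The largest falls among named genes were those of Scn4b, a sodium channel beta subunit, from 57.0 ± 10.9 to 3.24 ± 0.875 FPKM (SD, n = 5, log2 change -3.78), Ptprv (-3.76), the enkephalin precursor gene Penk (-3.41), Cd4 (-3.26), the G protein regulator gene Rgs9 (-2.94), the calcium release channel gene Ryr1 (-2.93), the phosphodiesterase gene Pde10a (-2.92), Lrrc10b (-2.90), Hipk4 (-2.88), the adenosine receptor gene Adora2a (-2.71), Ppp1r1b (-2.66) and Prima1 (-2.60). Among the largest rises were those of the myosin light chain gene Myl6b, from 5.41 ± 1.06 to 27.2 ± 8.33 FPKM (SD, n = 5, log2 change 2.09, limma adjusted p = 0.000343), Ifi27l2a (1.86), Smim24 (1.83), Oasl2 (1.67), Camk2n2 (1.62), Sidt1 (1.57), Prdm8 (1.54), Ndufaf6 (1.503), Ifi44 (1.41), Ifit1 (1.38) and Rtp4 (1.37). Oasl2, Ifi44, Ifit1, Rtp4 and Ifi27l2a are known to be induced by interferon. Ifi27l2a was at 1.96, 4.60, 4.06, 1.49 and 3.56 FPKM in the R6/2 libraries, at 0.505 in Control 2 and listed at 0 in the other control libraries. Smim24 was at 0.253, 0.498, 0.210 and 0.472 FPKM in Controls 1, 3, 4 and 5, listed at 0 in Control 2, and at 4.67, 2.83, 1.99, 3.69 and 5.30 FPKM in R6/2.

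Of 15905 genes tested with limma, 795 were higher and 1449 lower in R6/2 at an adjusted p under the threshold, so 64.6% of the calls were lower. Among these, 602 of the higher and 1245 of the lower genes had 5 R6/2 values all outside the range of the 5 controls. Over all genes tested, 13.1% had groups that did not overlap, where chance gives 0.794%. A change of at least 1.5-fold was seen in 374 of the higher and 1008 of the lower genes, and of at least 2-fold in 89 and 425. The share of lower calls depended on the scaling: it was 53.5% after quantile normalization (1111 higher, 1277 lower) and 39.8% when protein-coding genes were rescaled to 1 total (1644 higher, 1086 lower), which shifted the median of all genes by 0.106 on the log2 scale. Relative to the median of all genes, the medians of the gene lists moved little under that rescaling: -1.73 for the spiny neuron list, 0.758 for the interferon list and 0.156 for the proteasome list. With the signal of 4 cortical neuron genes in the model, which was higher in R6/2, 119 genes were higher and 526 lower. In that model the log2 change was -3.24 for Prima1 (limma adjusted p = 0.0666), 1.44 for Ifi27l2a (0.0638), 1.18 for Camk2n2 (0.1), 0.98 for Sidt1 (0.145), 0.94 for Prdm8 (0.182) and 1.64 for Ndufaf6 (0.134), each p the highest over the settings tried. The changes of Prima1 and Ndufaf6 were thus larger there, without passing. Leaving out each library in turn gave between 576 (without Control 3) and 890 (without Control 5) higher genes and between 1193 and 1518 lower genes (without the same libraries).

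Genes of spiny projection neurons, the GABA-releasing output neurons of the striatum, fell together. All 36 tested members of the list of genes expressed across spiny neurons fell, over all genes tested and adjusted over the list alone, with a median log2 change of -1.72 (camera adjusted p = 1.1e-41). Penk (ENSMUSG00000045573.9, GRCm38 chromosome 4, 4133531 to 4138819) fell from 757 ± 61.7 to 71.5 ± 15.6 FPKM (SD, n = 5, log2 change -3.41, SE 0.157, limma adjusted p = 4.1e-06). Pde10a (chromosome 17, 8525372 to 8986648), which breaks down cyclic nucleotides, fell from 220 ± 31.8 to 28.3 ± 5.23 FPKM (log2 change -2.92, SE 0.151, limma adjusted p = 5.12e-06). Ppp1r1b (chromosome 11, 98348404 to 98357796), which encodes the dopamine-regulated phosphoprotein DARPP-32, fell from 212 ± 50.7 to 32.7 ± 7.42 FPKM (log2 change -2.66, SE 0.216, limma adjusted p = 5.66e-05). Its exons overlap those of a gene on the other strand. The cannabinoid receptor gene Cnr1 (chromosome 4, 33924593 to 33948831) fell from 56.3 ± 7.81 to 11.9 ± 0.758 FPKM, with a limma adjusted p of 4.1e-06. The signal of 4 cortical neuron genes was higher in R6/2, and with it in the model 33 of the 36 genes were called lower, with a median of -1.44. Controls 2, 4 and 5, whose cortical signal lay nearest that of the R6/2 libraries (-0.0749, -0.0362 and -0.121), had spiny neuron means of 5.87, 5.88 and 5.69. Controls 1 and 3 had less signal (-1.33 and -1.70) and higher means (6.16 and 6.15). Among R6/2 libraries, R6/2 2 and 3 had the most signal (1.09 and 1.48) and the lowest means (4.04 and 3.76). The means thus tended to be lower within each group where the cortical signal was higher.

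Markers of the direct and the indirect output pathway were both lower. Of 10 direct-pathway markers, 7 fell over all genes tested and 7 adjusted over the list alone (median -0.75, camera adjusted p = 1.72e-05, adjusted p = 0.0997 with an estimated correlation). The D1 dopamine receptor gene Drd1 fell from 38.4 ± 9.60 to 7.56 ± 1.70 FPKM (SD, n = 5, log2 change -2.19, SE 0.192, limma adjusted p = 8.63e-05), the dynorphin precursor gene Pdyn fell by 2.48 and Slc35d3 by 1.82 on the log2 scale. Of 7 indirect-pathway markers tested, 6 fell, and 7 adjusted over the list alone (median -1.79, camera adjusted p = 1.03e-08, adjusted p = 0.0134 with an estimated correlation). The D2 dopamine receptor gene Drd2 (chromosome 9, 49340627 to 49408177) fell from 164 ± 16.4 to 29.2 ± 4.19 FPKM (log2 change -2.46, SE 0.113, limma adjusted p = 4.1e-06), and Adora2a (chromosome 10, 75316877 to 75334784) from 25.4 ± 4.55 to 3.05 ± 0.847 FPKM (log2 change -2.71, SE 0.169, limma adjusted p = 1.5e-05). The median of the indirect-pathway list was -1.05 with a pseudocount of 5 FPKM and -1.03 without the filter on low genes. The difference between the pathways was not tested.

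**Figure D2:**
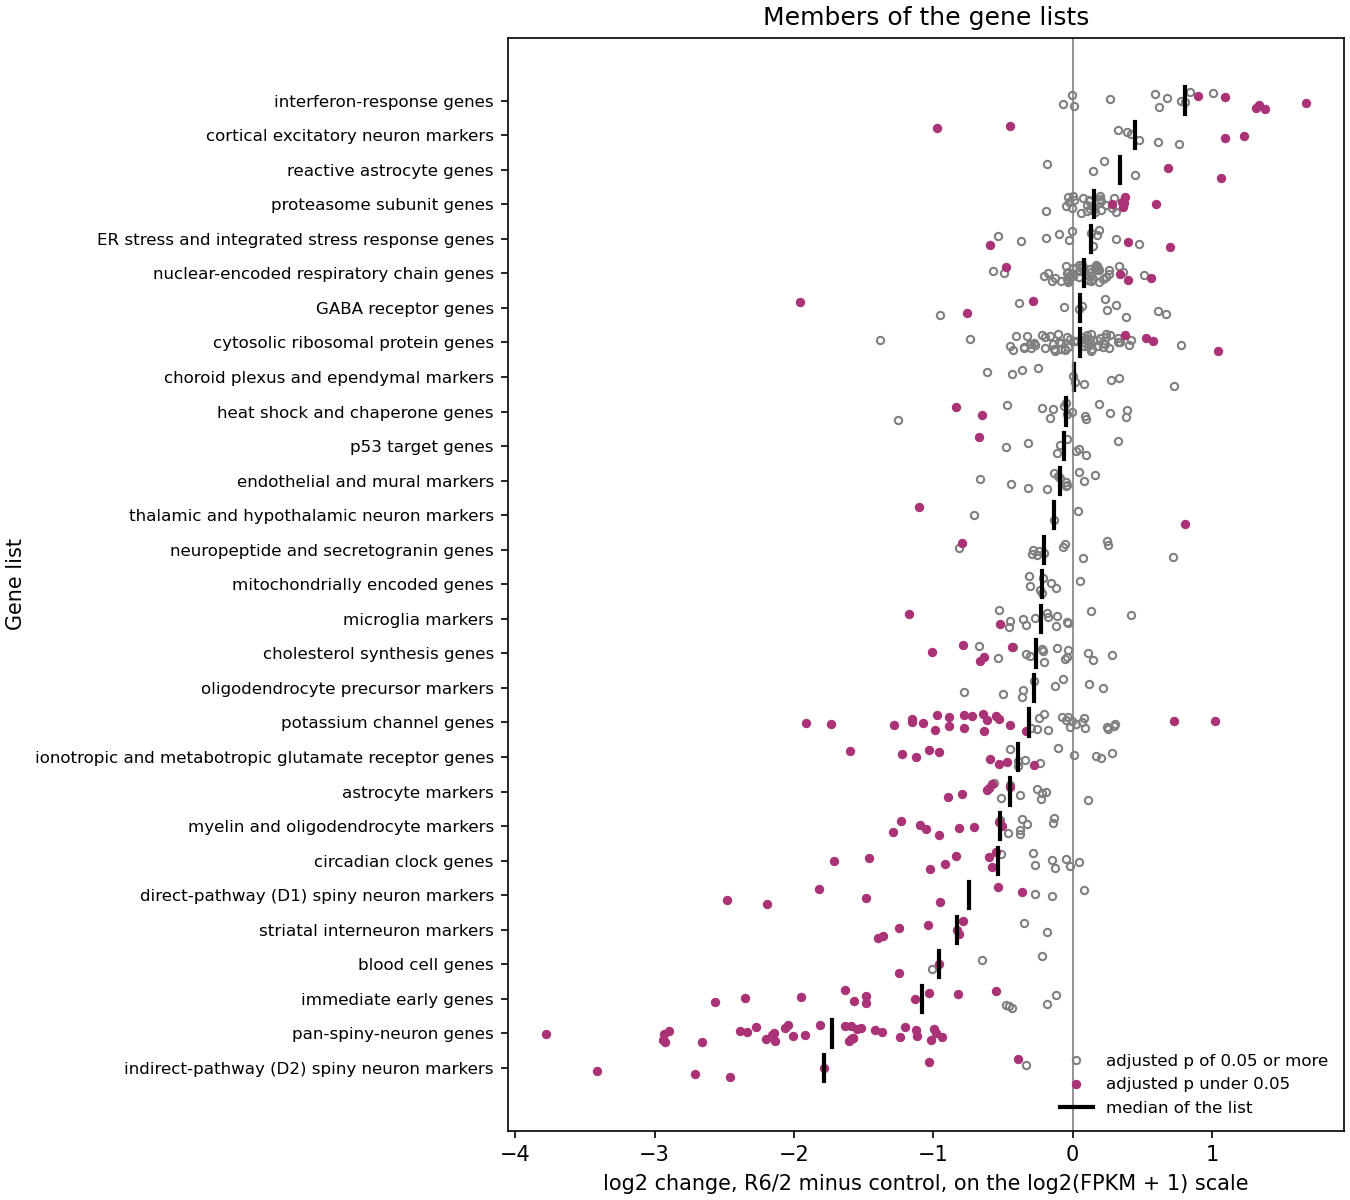
Log2 change (R6/2 minus control, log2(FPKM + 1) scale) of each tested member of the gene lists, with the list median marked. Members of the spiny neuron list lie below 0 throughout, between -3.78 and -0.94, and most interferon-response genes lie above 0 with a median of 0.81.

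Interneurons make up the small remaining share of striatal neurons. Of 9 interneuron markers tested, 7 fell, and 8 adjusted over the list alone (median -0.83, camera adjusted p = 6.69e-07). The median was -1.31 with a pseudocount of 0.1 FPKM and -0.48 with 5 FPKM. The choline transporter gene Slc5a7, used by cholinergic interneurons, fell from 4.401 ± 0.377 to 1.11 ± 0.108 FPKM (SD, n = 5, log2 change -1.36, limma adjusted p = 2.27e-05). The neuropeptide Y gene Npy fell by 1.25 and the neuronal nitric oxide synthase gene Nos1 by 1.04 on the log2 scale. For Nos1 the log2 change was -0.84 with the cortical signal in the model (limma adjusted p = 0.052, the highest over the settings tried).

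Interferon-response genes rose. Of 17 tested members, 6 rose and 0 fell, and 10 rose adjusted over the list alone (median 0.81, camera adjusted p = 8.92e-07, adjusted p = 0.0112 with an estimated correlation). Oasl2 (chromosome 5, 114896936 to 114912234), which belongs to the antiviral oligoadenylate synthetase family, rose from 2.52 ± 1.16 to 9.76 ± 1.40 FPKM (SD, n = 5, log2 change 1.67, SE 0.232, limma adjusted p = 0.00118), and Ifit1 from 0.435 ± 0.133 to 2.75 ± 0.547 FPKM (log2 change 1.38, SE 0.153, limma adjusted p = 0.000328). Ifit3 (1.32), Ifitm3 (0.90) and Ifi27 (1.09) were also among the 6. Ifit1 and Ifit3 had low values, and their changes were 2.43 and 2.15 with a pseudocount of 0.1 FPKM and 0.51 and 0.52 with 5 FPKM. With the cortical signal in the model the log2 change was 1.00 for Ifit3 (limma adjusted p = 0.053), 0.80 for Ifitm3 (0.102) and 0.87 for Ifi27 (0.154). Adding the cortical signal to the model left 3 of the genes called and a median of 0.842, where rescaling of protein-coding genes gave 11 called higher and a pseudocount of 5 FPKM a median of 0.48, with a camera adjusted p of 3.11e-06 in a range of 6.89e-09 to 0.0112 over the settings tried. Beside this, 2 of 16 microglia markers fell and none rose.

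Reactive astrocyte genes, which rise after injury, had 2 of 6 tested members higher, over all genes tested and adjusted over the list alone. Serpina3n, a protease inhibitor gene, rose by 1.06 (limma adjusted p = 0.00301) and the ceruloplasmin gene Cp by 0.69 (limma adjusted p = 0.0173) on the log2 scale, while the intermediate filament gene Vim had a log2 change of 0.45 (limma adjusted p = 0.317). Without R6/2 3 the change of Vim was 0.72 (limma adjusted p = 0.00689, in a range of 0.00689 to 0.504 over the settings tried). The list itself did not pass (median 0.34, camera adjusted p = 0.0551). It passed without R6/2 1 (0.0369), R6/2 2 (0.0333) or R6/2 3 (0.0247), and with the cortical signal in the model (median 0.62, 0.0446), in a range of 0.0247 to 0.175 over the camera settings tried, and gave 0.00402 in the self-contained test fry. For Serpina3n and Cp the log2 changes were 1.03 and 0.84 with the cortical signal in the model (limma adjusted p = 0.073 and 0.0862). The exons of Cp overlap those of Hps3.

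Genes induced by neuronal activity fell. Whether that fall is separate from the fall of the spiny neuron genes was not tested. Of 16 immediate early genes, 11 fell, and 12 adjusted over the list alone (median -1.08, and -0.70 with a pseudocount of 5 FPKM, camera adjusted p = 1.67e-10, adjusted p = 0.0112 with an estimated correlation). The synaptic scaffold gene Homer1 fell from 85.1 ± 15.6 to 26.4 ± 1.95 FPKM (SD, n = 5, limma adjusted p = 3.36e-05), the transcription factor gene Egr1 by 1.48 (limma adjusted p = 7.4e-05) and Egr2 by 2.56 on the log2 scale (limma adjusted p = 8.08e-05). Circadian clock genes also included 8 of 16 that fell, and 11 adjusted over the list alone (median -0.53, and -0.31 with a pseudocount of 5 FPKM, camera adjusted p = 1.3e-06). Npas2, a forebrain partner of the clock factor BMAL1, fell by 1.71, Arntl, which encodes BMAL1, by 0.92 and Per1 by 1.02 on the log2 scale (limma adjusted p = 3.98e-05, 0.000314 and 0.00066). The time of day at harvest is not given in the sources used here.

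In camera, the glutamate receptor and potassium channel lists fell and the GABA receptor list did not pass. Whether the falls of receptor and channel genes are separate from the fall of the spiny neuron genes was not tested. Of 19 glutamate receptor genes, 9 fell and 12 adjusted over the list alone (median -0.39, camera adjusted p = 2.17e-06). Among them Grm3 fell by 0.96, the kainate receptor gene Grik2 by 1.12 and Grm4 by 1.60 on the log2 scale (limma adjusted p = 8.08e-05, 0.000108 and 0.000189). Of 40 potassium channel genes, 20 fell and 2 rose, with the same counts adjusted over the list alone (median -0.31, camera adjusted p = 6.69e-07). Kcnip2, an auxiliary subunit of A-type channels, fell from 64.0 ± 11.3 to 16.2 ± 2.37 FPKM (SD, n = 5, limma adjusted p = 4.12e-05), Kcnh4 by 1.73 and Kcnh3 by 1.28 on the log2 scale. The G protein-gated channel gene Kcnj3 rose by 1.02 and Kcnj6 by 0.73 (limma adjusted p = 0.00512 and 0.0243), and Kcnj6 did not pass without Control 1, Control 3 or R6/2 1, 2, 3 or 4 (0.051 to 0.0609). With the cortical signal in the model the log2 change was 0.46 for Kcnj3 (limma adjusted p = 0.0263) and 0.28 for Kcnj6 (0.497). The median of the potassium channel list was -0.53 with a minimum mean of 5 FPKM, -0.49 with the cortical signal in the model and -0.20 after rescaling of protein-coding genes. Of 14 GABA receptor genes, 3 fell, and adjusted over the list alone 5 fell and 5 rose. The extrasynaptic delta subunit gene Gabrd fell by 1.96 (limma adjusted p = 2.01e-05), Gabra4 by 0.76 (0.000686) and Gabbr1 by 0.28 on the log2 scale (0.0273). The call of Gabbr1 was lost without R6/2 2 (log2 change -0.27, limma adjusted p = 0.0508), after quantile normalization (-0.13, 0.218), after rescaling (-0.17, 0.131) and with the cortical signal in the model (-0.30, 0.199), in a range of 0.0187 to 0.218. The GABA receptor list had a median of 0.06, a mean of -0.13 and the direction down in camera, which did not pass (adjusted p = 0.631), but it passed as lower in the self-contained test fry (0.0336). Its median ran from -0.13 with the cortical signal in the model to 0.16 after rescaling of protein-coding genes.

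The astrocyte and myelin marker lists were lower in camera. Of 15 astrocyte markers, 6 fell, and 9 adjusted over the list alone (median -0.45, and -0.28 with a pseudocount of 5 FPKM, camera adjusted p = 1.16e-05). The glutamate transporter gene Slc1a2 fell from 392 ± 30.6 to 212 ± 33.8 FPKM (SD, n = 5, limma adjusted p = 0.000668), the glutamine synthetase gene Glul by 0.60 (0.000876), the connexin gene Gja1 by 0.79 (0.00195) and the potassium channel gene Kcnj10 by 0.62 on the log2 scale (0.00278). Gfap, the classical marker of reactive astrocytes, was at 5.25 ± 0.983 FPKM in controls and 5.74 ± 1.12 in R6/2 (log2 change 0.11, limma adjusted p = 0.67, with changes of 0.03 without Control 4, 0.19 without Control 5, 0.19 without R6/2 2 and 0.02 without R6/2 4). For Gja1 and Kcnj10 the log2 changes were -0.63 and -0.51 with the cortical signal in the model (limma adjusted p = 0.0794 and 0.0947, the highest over the settings tried). Of 17 myelin markers, 9 fell, and 14 adjusted over the list alone (median -0.52, camera adjusted p = 1.8e-08, adjusted p = 0.0985 with an estimated correlation). Mobp fell by 1.05 and Ugt8a by 1.09 on the log2 scale (limma adjusted p = 0.000186 and 0.000314). None of 9 oligodendrocyte precursor markers passed limma over all genes or adjusted over the list alone (median -0.28, camera adjusted p = 0.284). Among them, the log2 change was -0.50 for Gpr17 (limma adjusted p = 0.0571), -0.78 for Vcan (0.136) and -0.36 for Pdgfra (0.228), and Gpr17 passed without Control 2 (0.0405) or Control 5 (0.04), without the trend (0.0476) and with array weights (0.0435).

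Microglia markers were barely lower as a list. Of 16 tested, 2 fell, also adjusted over the list alone (median -0.23, camera adjusted p = 0.0409, adjusted p = 0.0932 with an estimated correlation). The lysosomal marker gene Cd68 fell by 1.17 (limma adjusted p = 0.00376) and the purinergic receptor gene P2ry12 by 0.52 on the log2 scale (0.00454), while the cathepsin gene Ctss had a log2 change of 0.42 (0.0783) and passed without Control 5 (0.50, 0.0414), after quantile normalization (0.041) and after rescaling of protein-coding genes (0.0115). The list did not pass without Control 1 (camera adjusted p = 0.0526), Control 3 (0.05) or Control 5 (0.0807), nor after rescaling of protein-coding genes (0.0534), with a minimum mean of 5 FPKM (0.0566), with array weights (0.0573) or with the cortical signal in the model (0.127), in a range of 0.0119 to 0.127 over the camera settings tried, and gave 0.00168 in the self-contained test fry. Its median was -0.11 with a pseudocount of 5 FPKM and -0.15 after rescaling. Cd68 and P2ry12 had log2 changes of -1.10 and -0.42 with the cortical signal in the model (limma adjusted p = 0.0909 and 0.133), and the exons of P2ry12 overlap those of Med12l. None of 13 endothelial and mural markers changed in limma, over all genes or adjusted over the list alone (median -0.09, camera adjusted p = 0.601), with log2 changes of -0.32 for Pecam1, -0.66 for Abcb1a (-0.11 without Control 5) and -0.44 for Tek (-0.16 without Control 2). None of 10 choroid plexus and ependymal markers did either (median 0.01, mean -0.02, camera direction down, adjusted p = 0.869). Its leading members were Ccdc153 (log2 change -0.61, limma adjusted p = 0.114, but 0.0498 without R6/2 3), Rarres2 (-0.36, and -0.14 without Control 5) and Otx2 (0.33, with 0.55 without Control 2 and 0.17 without Control 4). Of 5 blood cell genes, 2 fell and 3 adjusted over the list alone (median -0.96, camera adjusted p = 0.0319, adjusted p = 0.142 with an estimated correlation). These were the haemoglobin genes Hba-a1 (-0.96) and Hbb-bs (-1.24), with Hbb-bt (-1.01) added by the list alone. Hbb-bs did not pass without Control 1, Control 4 or R6/2 1, 2 or 4 (limma adjusted p between 0.0512 and 0.06) or with the cortical signal in the model (log2 change -1.44, 0.142), nor did the list without Control 4 (camera adjusted p = 0.0534), Control 5 (0.0677) or R6/2 2 (0.0635). The median of the blood list was -0.44 with a pseudocount of 5 FPKM and -0.52 without the filter on low genes.

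Markers of neighbouring brain regions moved in both directions. Of 10 cortical excitatory neuron markers, 2 rose and 2 fell, with 4 and 2 adjusted over the list alone (median 0.45, camera adjusted p = 0.0824). The list passed without the filter on low genes (camera adjusted p = 0.0119, in a range of 0.0119 to 0.521 over the settings tried). The transcription factor gene Neurod2 rose by 1.23 (limma adjusted p = 0.0126), whereas Lamp5 fell by 0.97 and Tle4 by 0.45 on the log2 scale (0.00599 and 0.016). The vesicular glutamate transporter gene Slc17a7 was at 15.2 ± 5.85 FPKM in controls and 25.4 ± 5.29 in R6/2 (SD, n = 5, log2 change 0.77, limma adjusted p = 0.074, with 0.0365 without Control 4 and 0.0178 after rescaling of protein-coding genes). Adjusted for the cortical signal, the log2 change was 0.48 for Neurod2 (limma adjusted p = 0.246), -0.30 for Tle4 (0.32) and -1.004 for Synpo2 (0.0681). The mean of the 10 markers per library was 3.13 ± 0.299 in controls and 3.52 ± 0.297 in R6/2 on the log2 scale (SD, n = 5, exact permutation test, two-sided, p = 0.111). Over the 4 cortical genes used for the adjustment, which were chosen after their values were seen, the mean standardized signal was -0.653 ± 0.799 in controls and 0.653 ± 0.597 in R6/2 (SD, n = 5). Of 5 thalamic and hypothalamic markers, Synpo2 fell by 1.10 (limma adjusted p = 0.00207) and Slc17a6 rose by 0.81 on the log2 scale (0.0295), with Prkcd (-0.71) as a further fall adjusted over the list alone (list median -0.13, camera adjusted p = 0.566). Slc17a6 did not pass without Control 1, 2 or 3 or R6/2 1, 3 or 4 (0.0508 to 0.0681), without the filter on low genes (0.0559) or with the cortical signal in the model (log2 change 0.48, 0.451), and Prkcd passed limma over all genes without R6/2 4 (0.043). Of 41 developmental transcription factors only Onecut2 reached the filter, at 5.46 ± 1.05 and 5.48 ± 0.840 FPKM (SD, n = 5, log2 change 0.01, limma adjusted p = 0.98), so 0 members passed over all genes or adjusted over the list alone.

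**Figure D3:**
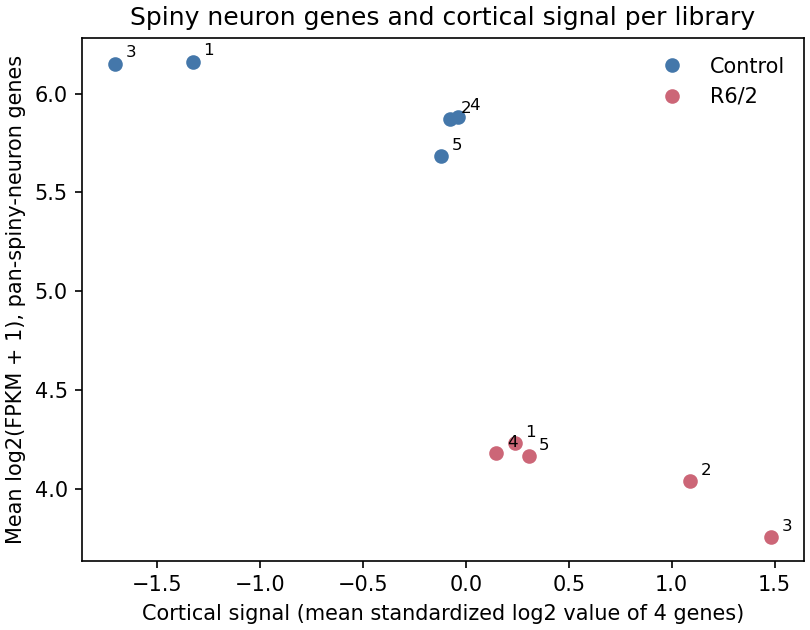
Signal of 4 cortical neuron genes (horizontal axis, mean standardized log2 value) and mean log2 value of the 36 spiny neuron genes (vertical axis) in each library. Controls lie between 5.69 and 6.16 on the vertical axis and R6/2 libraries between 3.76 and 4.23.

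Metabolic gene groups changed little apart from cholesterol synthesis. Of 20 cholesterol synthesis genes, 5 fell, and 7 adjusted over the list alone (median -0.26, camera adjusted p = 0.00235). The regulator gene Srebf2 fell by 0.78 (limma adjusted p = 0.00465), Msmo1 by 1.01 (0.00545), Dhcr7 by 0.43 (0.0107) and Fdft1 by 0.63 on the log2 scale (0.0136). Srebf2, Msmo1 and Dhcr7 had log2 changes of -0.57, -1.02 and -0.51 with the cortical signal in the model (limma adjusted p = 0.152, 0.0902 and 0.0706). The list median was -0.17 after rescaling of protein-coding genes. Of 51 nuclear-encoded respiratory chain genes, Ndufa8 (0.40), Ndufv2 (0.34) and Ndufb6 (0.57) rose and Atp5d (-0.48) fell, with 0 adjusted over the list alone (median 0.08, camera adjusted p = 0.0551). The list passed without Control 1 (0.0408), Control 4 (0.0384), Control 5 (0.0323) or R6/2 1 (0.0118), without the filter on low genes (0.021) and under all 3 other scalings (0.0405, 0.000779 and 0.015), in a range of 0.000779 to 0.434. Its median was 0.17 after quantile normalization and 0.19 after rescaling of protein-coding genes. Ndufv2 did not pass without Control 2 or R6/2 3 or 4 (limma adjusted p 0.0602 to 0.0617), Atp5d without Control 1, 2 or 3 or R6/2 1, 2 or 3 (0.0514 to 0.0793), and Ndufb6 without Control 2, 3 or 4 or R6/2 2, 3, 4 or 5 (0.0597 to 0.0956). None of 8 mitochondrially encoded genes passed over all genes or adjusted over the list alone (median -0.22, camera adjusted p = 0.278), with log2 changes of -0.32 for mt-Cytb, -0.31 for mt-Nd4 and -0.21 for mt-Co1. Without Control 5 these were -0.19, -0.15 and -0.09, and the list median was -0.08. Of 64 ribosomal protein genes, Rps9 (0.53), Rps21 (0.38), Rpl5 (1.05) and Rpl39 (0.58) rose, with 0 adjusted over the list alone (median 0.05, camera adjusted p = 0.284). Rps21 did not pass without Control 1, 3 or 4 or R6/2 3 or 4 (0.0513 to 0.0658), Rpl39 without Control 3 or 5 or R6/2 2, 3, 4 or 5 (0.0534 to 0.0738), and Rpl5 without any 1 library except Control 5 or R6/2 5 (0.0558 to 0.0756). In the model with the cortical signal the log2 change was 0.31 for Ndufa8 (limma adjusted p = 0.316), 0.24 for Ndufv2 (0.414), 0.51 for Ndufb6 (0.339), -0.34 for Atp5d (0.42), 0.51 for Rps9 (0.161), 0.24 for Rps21 (0.439), 0.77 for Rpl5 (0.392) and 0.26 for Rpl39 (0.536). Without the filter on low genes, limma gave adjusted p = 0.0569 for Atp5d, 0.0685 for Ndufb6, 0.0563 for Rpl5 and 0.0527 for Rpl39. Atp5d was also lost after quantile normalization (0.0774) and rescaling (0.0549), Ndufb6 without the trend (0.0507), and Ndufb6 and Rpl39 with array weights (0.0549 and 0.0548).

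Proteasome genes rose slightly. Of 31 subunit genes, 6 rose and 0 fell, and 7 rose adjusted over the list alone (median 0.15, camera adjusted p = 0.000459, adjusted p = 0.0897 with an estimated correlation). Psmc3, an ATPase of the regulatory particle, rose from 111 ± 10.1 to 170 ± 25.5 FPKM (SD, n = 5, log2 change 0.60, limma adjusted p = 0.00686), Psmc2 by 0.28 (0.0303) and Psmb4 by 0.36 on the log2 scale (0.0308). Psmc2 did not pass without Control 1 or 3 or R6/2 3 or 4 (0.0501 to 0.055), nor Psmb4 without Control 2 or 4 or R6/2 2, 3, 4 or 5 (0.0516 to 0.0625) or with array weights (0.0623). The list median was 0.26 after rescaling of protein-coding genes. Heat shock genes did not move as a list (median -0.05, camera adjusted p = 0.674, with medians of 0.06 after rescaling of protein-coding genes, 0.01 with the cortical signal in the model and 0.000563 after quantile normalization). Of 17 tested, the co-chaperone genes Dnajb5 and Hsph1 fell by 0.83 and 0.65 (limma adjusted p = 0.0204 and 0.0305), and adjusted over the list alone 3 fell and Hsp90aa1 rose (log2 change 0.38, adjusted over all genes 0.0515). Over all genes Hsp90aa1 passed limma without R6/2 4 (0.033), with a pseudocount of 0.1 FPKM (0.0469), with a minimum mean of 5 FPKM (0.0395) and under the 3 other scalings (0.0417, 0.0173 and 0.00462). Dnajb5 did not pass without Control 1 (log2 change -0.78, 0.0539), nor Hsph1 without Control 1, 3 or 5 or R6/2 1, 4 or 5 (0.0593 to 0.0735), after quantile normalization (0.0565) or without the filter on low genes (0.052). Among 15 endoplasmic reticulum stress genes, Atf4 and its target Asns rose by 0.70 and 0.40 (limma adjusted p = 0.00419 and 0.0409) and Ddit3, which encodes the factor CHOP, fell by 0.59 on the log2 scale (0.00901), with the same counts adjusted over the list alone (median 0.13, camera adjusted p = 0.601). Asns did not pass without any 1 library except Control 3 or R6/2 4 (0.0562 to 0.0879), nor without the filter on low genes (0.0599) or the trend (0.0535). Atf4, Ddit3 and Psmc3 had log2 changes of 0.43, -0.50 and 0.46 with the cortical signal in the model (limma adjusted p = 0.128, 0.185 and 0.185). That model gave 0.27 for Psmc2 (limma adjusted p = 0.275), 0.34 for Psmb4 (0.288), -0.93 for Dnajb5 (0.149), -0.47 for Hsph1 (0.396) and 0.51 for Asns (0.139). Of 10 p53 target genes, Plk2 fell by 0.67 on the log2 scale (limma adjusted p = 0.000928), 1 also adjusted over the list alone, while Zmat3 (-0.32, 0.104) and Trp53inp1 (0.32, 0.162, and 0.0275 without Control 5) did not pass (median -0.06, camera adjusted p = 0.363). The p53 list passed in the self-contained test fry (0.00502), and its median was 0.03 after rescaling of protein-coding genes. Of 13 neuropeptide and secretogranin genes, the prohormone convertase gene Pcsk2 fell by 0.79 on the log2 scale (limma adjusted p = 8.04e-05), 1 also adjusted over the list alone, with log2 changes of -0.29 for Scg2 (0.0603, with 0.041 without Control 1 and 0.0454 with a minimum mean of 5 FPKM) and -0.20 for Scg3 (0.154). The list had a median of -0.20 (camera adjusted p = 0.218) and passed with the cortical signal in the model (median -0.30, camera adjusted p = 0.037) and in the self-contained test fry (0.0187).

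The endogenous huntingtin gene Htt (ENSMUSG00000029104.15, chromosome 5, 34761740 to 34912534) was at 16.2 ± 0.697 FPKM in controls and 16.6 ± 1.30 in R6/2 (SD, n = 5, log2 change 0.03, SE 0.0702, limma adjusted p = 0.825). Gm12695 (ENSMUSG00000078639.1, chromosome 4, 96723647 to 96785186), the gene at the known insertion site of the R6/2 transgene, lay below the filter on low genes. It was at 2.29, 1.80, 2.34, 1.74 and 0.699 FPKM in the R6/2 libraries, at 0.0688 in Control 1 and listed at 0 in the other controls (exact permutation test, two-sided, p = 0.00794, the smallest p this design allows). Without the filter its log2 change was 1.41 (SE 0.176, limma adjusted p = 0.00129).

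In camera at the preset correlation, 13 of the 29 lists were lower and 2 higher in R6/2. With that preset, 58 of 80 splits that mix the groups 3 and 2 also called at least 2 lists in 1 direction. Its p-values are therefore not taken at face value. With an estimated correlation 9 of the lower lists held, at camera adjusted p between 0.00708 and 0.021. These were the indirect-pathway, spiny neuron, interneuron, astrocyte, immediate early, clock, cholesterol, glutamate receptor and potassium channel lists. Of the higher lists, the interferon list held. The mean of each list per library, which sets R6/2 against control without reference to other genes, was compared by exact permutation tests, two-sided, over the 29 lists: after Benjamini-Hochberg adjustment 3 lists were higher (interferon, proteasome and reactive astrocyte), 16 lower and 10 neither. The 16 were the 13 that camera called lower and the oligodendrocyte precursor (0.0271), endothelial and mural (0.0384) and p53 target lists (0.0485). These means carry any difference in scaling between libraries. After rescaling of protein-coding genes the medians of the last 3 lists were -0.217, 0.00563 and 0.03, so the lower endothelial and p53 means depended on the scaling. The smallest p was 0.00794 (adjusted 0.0153, exact permutation test).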

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

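The tests of the share of spiny neurons, of microglia, of the correlation of the cortical markers, of the genes around Gm12695 and of shared windows were chosen after the results were seen, while the adjustment for cortical signal and the other scalings are described with the processing. The values below stood far from the other 4 libraries of their group, by a gap that chance gives in about 1 in 20 groups. In all, 220 groups were checked and 19 such values were found, where chance gives 11.

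Control 5 stood apart most often. It had 38.8 FPKM for Scn4b (57.1 to 66.6 in the other controls), 10.15 for Ryr1 (15.9 to 18.7), 9.99 for Gja1 (14.5 to 15.3), 6.71 for Srebf2 (9.73 to 10.9), 44.5 for Kcnip2 (66.0 to 73.6), 21.5 for Abcb1a (1.76 to 2.90), 2.485 for Trp53inp1 (1.385 to 1.52), 14330 for mt-Nd4 (8101 to 8507) and a total of 2309000 (1638000 to 1823000). The other controls that stood apart were Control 2 with 0.505 FPKM for Ifi27l2a (listed at 0 in the others) and 139.3 for Hsp90aa1 (178 to 194), Control 1 with 0.0688 for Gm12695 (listed at 0 in the others), Control 3 with 39.9 for Zmat3 (29.9 to 32), and Control 4 with 24.7 for Npy (30.75 to 33.6). Among R6/2 libraries, R6/2 4 had 10.55 FPKM for Cnr1 (12.1 to 12.5), R6/2 5 had 10.58 for Dnajb5 (20.2 to 23.3), R6/2 1 had 12.8 for P2ry12 (9.36 to 9.96), R6/2 2 had 34.35 for Ctss (27.1 to 28.7) and R6/2 3 had 1.23 for Synpo2 (2.63 to 2.96). Gm12695, which was left out of the gene tests by the filter on low genes, had a mean of 1.776 FPKM in R6/2 and was listed at 0 in 4 of 5 controls.

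The fall of spiny neuron genes was weighed first. More cortical tissue in R6/2 pieces is argued against as the sole source, since the median was -1.44 with the cortical signal in the model. The 4 genes of that signal were chosen after their values were seen, however, and its values in R6/2 all lay above those in controls. The median was -1.70 under median-ratio scaling, which moved all genes by only 0.0167, and -1.62 under the rescaling of protein-coding genes, which moved them by 0.106, so neither scaling removed the fall. A lower share of spiny neurons with no change in any cell predicts that other cell types keep their ratios. Endothelial minus myelin scores differed by 0.503 on the log2 scale (exact permutation test, two-sided, p = 0.00794), so more than that share changed. As the test uses no spiny neuron genes, it cannot say how much of their fall came from a lower share. A change of transcription inside spiny neurons of the genotype stays as a hypothesis that may hold and was not tested. Splits of the 10 libraries into 5 and 5 were counted by their calls in 1 direction, higher or lower. Of 100 such splits, only the real one (1 of 100) reached 795 genes and only the real one (1 of 100) reached 1449 (highest other 5). Chance is thus an unlikely source of both counts, although the other splits mix the genotypes, which adds to their spread.

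The rise of interferon genes was weighed next. A larger share of microglia, which express many of these genes, is argued against by microglia scores that were lower in R6/2 (difference -0.262, exact permutation test, two-sided, p = 0.00794), although activated microglia could lower those markers. These scores carry any difference in scaling. The list's fall was weak, with a median of -0.15 after rescaling of protein-coding genes (camera adjusted p = 0.0534). In the main fit its camera adjusted p was 0.0932 with an estimated correlation. The cortical signal in the model left the median at 0.842, which argues against cortical tissue as the sole source of the rise. That signal did not overlap between the groups (at most -0.0362 in controls, at least 0.148 in R6/2), so the model cannot fully separate it from genotype. An interferon response of the genotype stays as a hypothesis that may hold, and the cell type it would occur in stays open. For the number of lists called higher by camera chance cannot be excluded. The splits were counted by their calls in 1 direction, higher or lower. As many came from 78 of 100 splits, the real one included (real 2, highest other 16), 58 of them among the 80 splits that mix the groups 3 and 2. As many lists in 1 direction as were called lower came from 6 of 100 splits, the real one included (real 13, highest other 16). The 5 others of these kept 4 libraries of each group together and so held most of the genotype difference, whereas 0 of the 80 splits of 3 and 2 reached 13 (highest 9).

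The cortical markers were weighed last. The mean of all 10 markers, fixed before the data were examined, did not differ by the exact permutation test (two-sided, p = 0.111). More cortical tissue in the R6/2 pieces predicts that the markers rise and fall together across libraries of 1 group. Their mean correlation within groups was 0.417, above the 95th percentile of 10000 random lists (0.106). Other lists also had high estimated correlations, such as 0.507 for spiny neuron, 0.453 for thalamic and hypothalamic and 0.391 for myelin genes. The comparison with random lists therefore cannot decide about varying amounts of cortex. Lamp5 and Tle4 fell while Neurod2 rose, so the markers did not all rise. Whether striatal cells also express Lamp5 and Tle4 was not tested, so their fall cannot decide about a uniform admixture. A change of these genes within striatal cells of the genotype may also contribute and was not tested.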

How the results depend on the processing

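Of 84 named genes called, 48 stayed past the threshold with the same sign in each alternative, and 10 of 15 called lists did. Over alternatives, 2093 values for named genes kept sign and side of the threshold, 122 lost the call, 19 gained it and 4 turned sign, against 623, 15, 18 and 6 for lists. The median of the spiny neuron list lay between -1.98 (pseudocount 0.1 FPKM) and -1.44 (cortical signal). The number of higher genes was 370 with the replicate block, 119 with the cortical signal and 1644 after rescaling of protein-coding genes, and the number of lower genes was 526 with the cortical signal. The block uses degrees of freedom, the covariate is partly confounded with genotype and the rescaling shifts all genes upward. The replicate block also gave 975 lower genes and ended 15 named calls, whereas the cortical signal ended 36, the most of any setting. Libraries with the same number had correlations of -0.021, -0.0148, -0.0528, -0.0198 and 0.0495 after group means were removed, and not every library was closest to its own number, so the numbers are not taken as pairs. Lists called higher numbered 5 without the filter on low genes (the cortical, respiratory chain and developmental factor lists were added, the last with 23 genes where 1 had passed the filter), 1 with an estimated correlation and between 2 and 4 when 1 library was left out (4 without R6/2 1). The cause was not tested. The direction turned for Onecut2 (log2 change -0.0608 to 0.10 with 1 library left out, below 0 without Control 1 or 2 or R6/2 4 or 5) and, by camera and here with their medians, for the choroid plexus list (-0.145 to 0.305 with 1 library left out; 0.305 without Control 2 and 0.210 without R6/2 4) the endoplasmic reticulum stress list (-0.00583 to 0.162; 0.06 without Control 2), the cortical list (-0.0909 with the cortical signal, which is built from its members) and the heat shock list (0.000563 after quantile normalization, 0.0144 with the cortical signal). Apart from the cortical list the cause was not tested. The covariate for sex was not run, because all libraries expressed Y-linked genes with low Xist (signal between -3.99 and -2.23). Xist was highest in R6/2 4 (2.44 FPKM) and Control 1 (1.06 FPKM), and at most 0.536 FPKM in the other libraries. Depth is unknown, so its effect on low genes could not be measured.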

Other observations

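Genes with the symbol root Rgs, mostly regulators of G protein signalling, which shorten the response of dopamine and other receptors, fell as a family. Of 17 Rgs genes 10 fell and 1 rose, with a median log2 change of -1.12 (camera adjusted p = 1.09e-05 over 209 families that share a symbol root, 0.337 with an estimated correlation). The family includes Rgs7bp (-1.33), which encodes a binding protein of such regulators. Rgs4 and Rgs9 are also in the spiny neuron list, so the family's fall is not separate from the fall of that list. Rgs4, Rgs2 and Rgs14 fell by 2.34, 1.87 and 1.43 on the log2 scale, while Rgs19 rose by 0.85 (limma adjusted p = 0.00921). With the cortical signal in the model the log2 change of Rgs19 was 0.64 (limma adjusted p = 0.218). These families and genes were chosen after their values were seen.

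Some subunit genes of RNA polymerases rose. Of 26 Polr genes 4 rose and 0 fell (median 0.197, camera adjusted p = 0.0202, 0.379 with an estimated correlation), and Polr2a, the catalytic subunit gene of RNA polymerase II, rose from 9.63 ± 1.51 to 21.9 ± 2.21 FPKM (SD, n = 5, log2 change 1.11, limma adjusted p = 0.000236). Polr2m (0.56), Polr1d (0.43) and Polr2i (0.84) were the others, and Polr2i did not pass without Control 1, 3 or 4 or R6/2 1, 4 or 5 (limma adjusted p between 0.0564 and 0.0748) or without the filter on low genes (0.052). Of 18 clustered protocadherin beta genes, which label single neurons, Pcdhb8 (0.85), Pcdhb10 (0.46) and Pcdhb22 (0.39) rose (camera adjusted p = 0.00992, 0.379 with an estimated correlation), and Pcdhb8 did not pass without R6/2 1, 3 or 4 (limma adjusted p between 0.0557 and 0.0591). Pcdhb10 did not pass without Control 2, 3 or 5 or R6/2 1, 2, 3 or 4 (0.0505 to 0.0671), nor Pcdhb22 without Control 1, 2, 4 or 5 or R6/2 1, 2 or 3 (0.0543 to 0.0748), and without the filter on low genes neither passed (0.0676 and 0.0643). With the cortical signal in the model the log2 change was 0.95 for Pcdhb8 (limma adjusted p = 0.164), 0.43 for Pcdhb10 (0.333), 0.42 for Pcdhb22 (0.211), 0.88 for Polr2i (0.219), 0.38 for Polr1d (0.218) and 0.33 for Polr2m (0.089).

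Gm25177, a small nuclear RNA gene that shares exon sequence with Tbc1d5, was listed at 0 in all 5 controls and was at 112.7, 90.7, 93.5, 34.3 and 35.1 FPKM in R6/2 (limma adjusted p = 6.95e-06). The Y-linked gene Eif2s3y was at 23.9 ± 4.04 FPKM in controls and 33.2 ± 3.47 in R6/2 (SD, n = 5, log2 change 0.47, limma adjusted p = 0.0379), and did not pass without Control 1 or 2 or R6/2 1, 2, 3 or 5 (0.0551 to 0.0834), without the filter on low genes (0.0587) or with the cortical signal in the model (log2 change 0.52, 0.222). Both were chosen after their values were seen.

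The tests of position were chosen after the results were seen. Genes within 10 Mb of Gm12695 were called in 6.67% of cases (5 of 75) and genes elsewhere in 14.1% (Fisher's exact test, two-sided, p = 0.0668), which cannot tell whether genes flanking the insertion site change with the transgene. Over 274 windows of 10 Mb the smallest Holm adjusted hypergeometric p for an excess of called genes was 0.144 (chromosome X from 130 Mb, 17 of 52 genes), and 14 windows had an unadjusted p under 0.05, so a clustering of changed genes on the genome was not shown.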
